A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

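RNA was measured in 6 cultures of Saccharomyces cerevisiae BY4743, 3 treated with linoleic acid hydroperoxide (LoaOOH) and 3 treated with its solvent, methanol, and each culture had its own array. Per the labels' protocols, cells were broken with glass beads in TRIzol, total RNA was cleaned on silica columns, and biotinylated cRNA was made by the standard Affymetrix protocol. The deposited values are on the log2 scale, and the authors made them with RMA; the submitters' processing notes name RMA and Partek without saying which step each did. RMA subtracts background, quantile-normalises the arrays and summarises the probes of each probe set. The versions of both, the set of arrays normalised together and any probe mask are not given in the sources used here. Because quantile normalisation gives arrays nearly the same distribution, a change shared by most messages would be hidden in these values. The array medians lay between 10.588 and 10.628 with no further scaling, and the values ran from 2.434 to 15.14.

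The table held 5900 probe sets. Of these, 184 were Affymetrix control probe sets, and 218 had no gene in the platform annotation table and were kept out of the main test. The remaining 5498 each named 1 gene, 5449 genes in all, and no probe set named several. All 5498 gene identifiers matched the yeast gene table of assembly R64, which replaced 12 older symbols and was used for names, neighbouring genes and gene lengths. The sources name no genome build for the array, so positions are not given. The annotation marked no probe set as one of Schizosaccharomyces pombe, which this array design also carries. Only the 218 without a gene could be of that species, and none was used as such.

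Groups and replicate numbers came from the sample titles. The labels describe the replicates as biological and give an aliquot of 50 mL for each sample. The p-values measure the spread between these samples, here called cultures. Whether aliquots shared a parent culture is not known here, and if so that spread is not one between independent cultures. No array duplicated another: at most 0.109% of probe sets had the same value on any pair of arrays. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.0527.

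The LoaOOH group was compared with the methanol group by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no covariate, two-sided), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are LoaOOH minus methanol, with the standard error (SE) from the moderated variance. A fold is 2 to the power of the log2 difference. Where a group mean lay below the brightest negative control probe set, at a mean of 5.146, the fold was computed against that level and is a lower bound. A set of 23 gene lists was tested with limma's camera at its preset inter-gene correlation of 0.01, on the brightest probe set of each gene, with adjustment over the 23 lists. Camera compares a list with all other genes. Beside it stood camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance 1 way. A single value per array, such as the mean of a class of control probe sets, was compared by an exact two-sided permutation test, for which 3 against 3 arrays allow no p below 0.1.

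The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes that have a standard name, were called and whose groups do not overlap. From each list it took up to 3 called members with the largest change in the main direction and the called member with the largest change the other way, and it took all measured members of lysine biosynthesis. This named 100 different genes. Other list members named because 5 or fewer of a list went a given way were chosen after their values were seen, as were LEU2, HIS3 and URA3.

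The procedure was tested on simulated data for this comparison, with 5498 probe sets on 6 arrays. Of 50 probe sets changed by 0.25 on the log2 scale 62% were recovered, and of 50 each changed by 0.5, 1 and 2 it recovered 100%. It called 12 of 5298 probe sets that had no simulated change. In the list test on 5449 genes, a list shifted by 0.5 was called and 0 of the 22 others were called by camera. The simulated genes varied independently and most had no change, so this does not test the preset correlation where genes vary together.

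The alternatives were quantile normalisation of the deposited values, centring on array medians, a variance trend with robust fitting, no variance moderation, array weights, leaving out the dimmest 25% of probe sets, leaving out probe sets that may cross-hybridise, an adjusted p under 0.01, limma's treat against a log2 change of 0.5, the replicate number as a block, each array left out in turn, and other list tests. Scaling to the poly-A spike-ins, adding the unnamed probe sets and leaving out the 126 probe sets below the brightest negative control were chosen after seeing the data. Figures and the copy of the submitters' tool names were made in Python 3.11.15.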

Results

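Expression was profiled in BY4743, a diploid laboratory strain of Saccharomyces cerevisiae, after exposure to LoaOOH, a lipid hydroperoxide that forms when linoleic acid is oxidised. Exponential cultures in minimal medium at 30 °C received 75 µM LoaOOH, a dose that the labels call arresting, or methanol alone at OD600 1.0, and were harvested 1 h later. Each group held 3 biological replicate cultures, each on 1 Affymetrix Yeast Genome 2.0 array, a 1-colour oligonucleotide array with RMA values on the log2 scale. Across 5498 probe sets, each for 1 gene, arrays of the same group correlated at 0.99768 to 0.99911 and arrays of different groups at 0.9505 to 0.95431. The comparison asks which messages differ between LoaOOH-treated and solvent-treated cells at this dose.

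Relative to the typical message, LoaOOH-treated cells held more message for iron acquisition, sulfur assimilation, synthesis of amino acids other than lysine, multidrug resistance and peroxide defence, and less for G1 and S phase and for protein folding in the endoplasmic reticulum. With an estimated correlation the iron, sulfur, amino acid and antioxidant lists lose their call (adjusted p = 0.11, 0.11, 0.143 and 0.11). FIT2, a cell wall mannoprotein that retains siderophore iron, rose 47.5-fold (log2 difference 5.57, SE 0.041, n = 3 per group, adjusted p = 4.66e-12). OYE3, an NADPH oxidoreductase that reduces unsaturated carbonyls, rose 19.3-fold, and SRX1, the sulfiredoxin that restores overoxidised peroxiredoxins, rose 18.1-fold. BIO5, which takes up a biotin precursor, fell 25.4-fold (log2 difference -4.67, SE 0.069, adjusted p = 3.41e-10), and MCD1, a cohesin subunit made for S phase, fell 5.37-fold.

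Among genes with a standard name the other large rises were YHK8, a presumed multidrug transporter (log2 difference 4.08), HMX1, the haem oxygenase that recovers iron from haem (4.02), JEN1, the lactate and pyruvate permease (3.75), PRM7 (3.71), and ISU2, a scaffold for iron-sulfur cluster assembly (3.37). PRM7 has a second probe set, which gave 3.65. RGI2 and SUL1, a sulfate permease, lay below the brightest negative control probe set in the methanol cultures, so their folds are bounds: at least 6.83-fold and at least 5.36-fold higher. Their places among the largest rises are not firm, as both bounds lie below the rise of RSB1 (7.28-fold). Falls of over 4-fold included BIO3 (-2.82) and BIO4 (-2.29), which make biotin and lie next to BIO5 on the chromosome. They also included TOS6 (-2.63) and TOS4 (-2.40), which are targets of the G1 regulator SBF, ACM1, an inhibitor of the anaphase-promoting complex (-2.52), SPS4, a sporulation gene (-2.41), POL30, the replication clamp PCNA (-2.18), and the checkpoint kinase gene DUN1 (-2.15). In each of these 20 genes the 3 LoaOOH cultures lay beyond all 3 methanol cultures, because the naming rule took only such genes. YJL213W, which has only a systematic name and was added after its value was seen, rose by 3.55, more than ISU2.

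**Figure D1:**
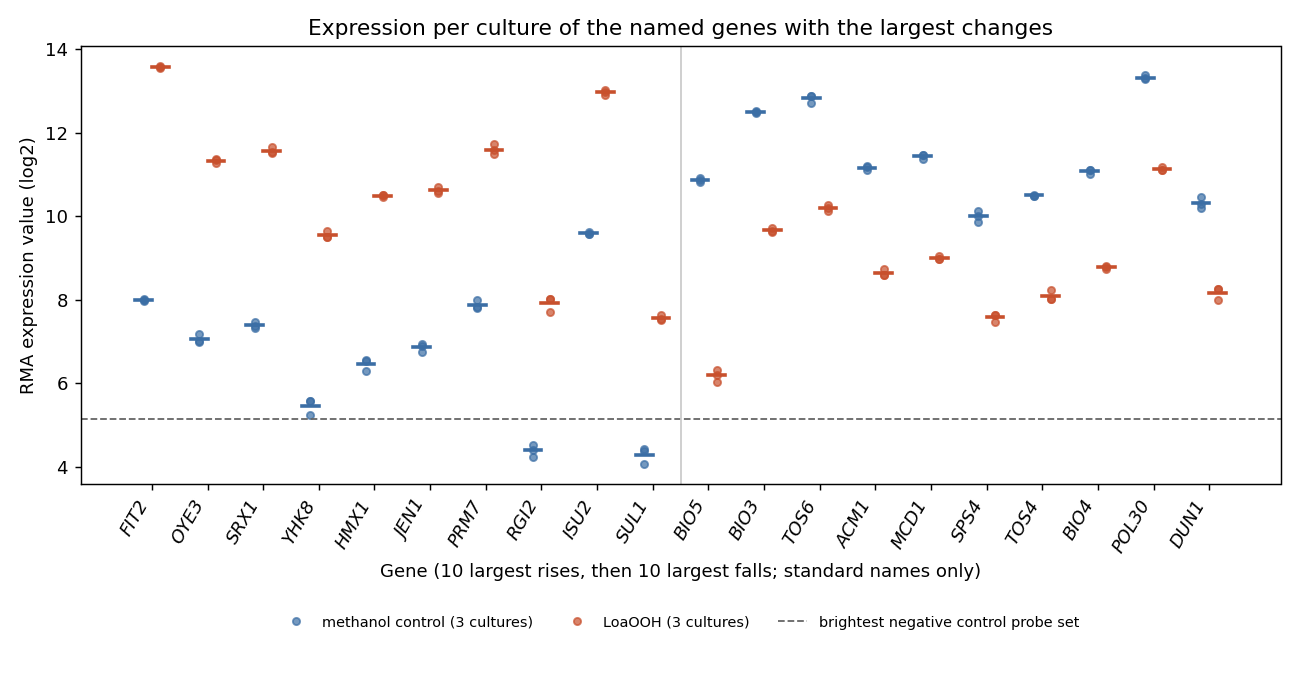
RMA expression (y axis, log2) of the 10 genes with the largest rises and the 10 with the largest falls among genes with a standard name (x axis), with a point per culture, 3 methanol and 3 LoaOOH, and a bar at each group mean; the dashed line is the brightest negative control probe set. Within each gene the groups do not overlap, which the rule for naming genes required, and FIT2 goes from a mean of 8.002 to 13.573. RGI2 and SUL1 start below the dashed line, so their ranks are not firm.

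Most messages differed between the groups. Of 5498 probe sets, 4327 (78.7%) were called by limma, 2022 higher and 2305 lower. The groups did not overlap in 4459 (81.1%), where chance gives 10%. Most differences were small: 2494 called probe sets differed by under 0.5 on the log2 scale and the median called difference was 1.35-fold. At least 2-fold differences numbered 504 (276 higher, 228 lower), and at least 4-fold differences 61 (48 higher, 13 lower).

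Control probe sets bear on these directions. The 36 poly-A spike-in probe sets, for bacterial messages added to the RNA, averaged 7.44 ± 0.165 (SD, n = 3) in the methanol arrays and 6.93 ± 0.125 in the LoaOOH arrays, and all 36 were lower (exact permutation p = 0.1, the smallest possible here). The 17 ribosomal RNA probe sets fell by 0.639 on the log2 scale, again all lower with the same exact p, while hybridisation controls differed by -0.0156 (exact p = 0.8). Scaled to the spike-ins, every log2 difference moves up by 0.518, the median of all tested goes from -0.0341 to 0.484, and 3625 probe sets (89.6% of those called) are higher and 422 lower, against 46.7% higher in the deposited scaling. Directions below are those of the deposited scaling, hence relative to the typical message, and the spike-in scaling's counts are given with each list, with its median where that turns. The difference between 3' and 5' probe sets of a message is a sign of RNA or labelling quality. It moved by 0.584 for SRB4, 0.399 for the dap spike-in, 0.163 for SPT15, -0.0338 for RIP1, -0.137 for ACT1 and -0.147 for WBP1 (exact p = 0.1 each). For EAF5 it moved by 0.03 (exact p = 0.2) and for TDH1 by 0.00117 (exact p = 1).

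**Figure D2:**
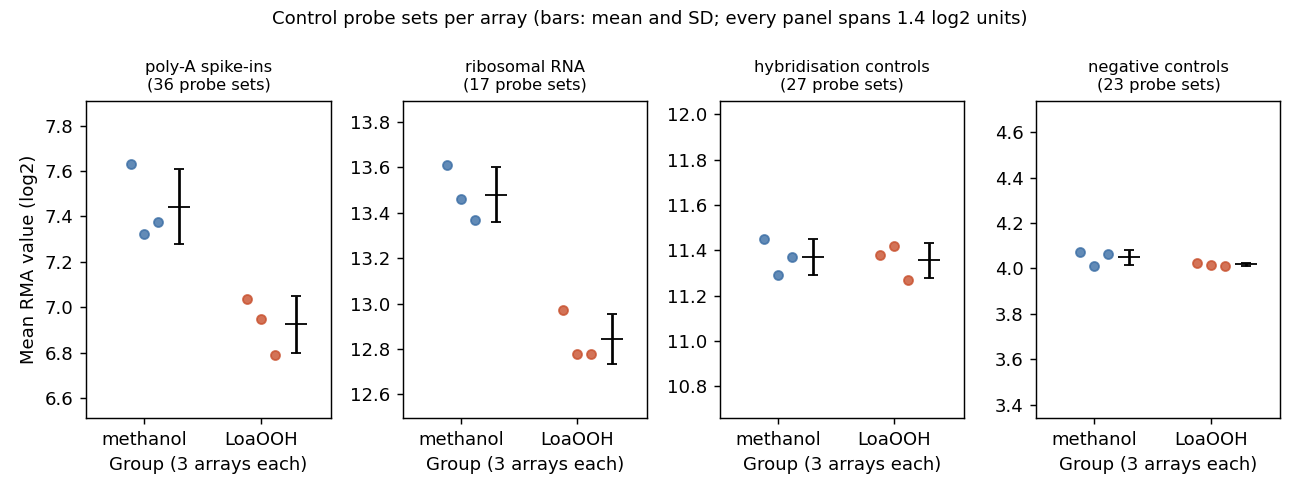
Mean RMA value (y axes, log2) of 4 classes of control probe sets in each array, by group (x axes), with a point per array and a bar for the mean and SD of 3 arrays. Spike-in and ribosomal RNA means are lower in every LoaOOH array than in every methanol array, and hybridisation and negative controls overlap (differences of -0.0156 and -0.031).

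Camera called 14 of the 23 gene lists, 11 higher and 3 lower, and with an estimated correlation 3 calls held: Pdr1 and Pdr3 targets, the unfolded protein response, and G1 and S phase. Fry, which does not compare a list with other genes, called 22, all but meiosis and sporulation. For 19 lists the counts of called members were the same adjusted over the list alone, and the others are given with their list.

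Among the 23 lists G1 and S phase genes had the lowest median. Of 43 measured, 37 fell, 0 rose and 6 were not called (median log2 difference -1.01, camera adjusted p = 8.34e-09, and 0.0367 as adjusted p with an estimated correlation). Besides MCD1, TOS4 and POL30, this group spans cyclin, DNA polymerase and ribonucleotide reductase genes. In the spike-in scaling the median was -0.494, with 25 lower and 9 higher. Camera did not call the genes of G2, M and M/G1, with 14 of 43 higher and 19 lower (15 and 20 adjusted over the list alone; median -0.07, camera adjusted p = 0.605; fry down, adjusted p = 0.000725; spike-in median 0.452, with 28 higher and 2 lower). Among them PCL9, a cyclin of late mitosis and G1, fell by 1.46 and SIC1, the inhibitor of S phase kinase, fell by 1.11 on the log2 scale, and TEC1 rose by 0.73.

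Genes of the unfolded protein response and endoplasmic reticulum folding fell in 22 of 24 cases (median -0.90, camera adjusted p = 1.92e-06, and 0.0367 as adjusted p with an estimated correlation). The lowest differences were those of MPD1, a disulfide isomerase (-1.92), SIL1, the exchange factor of the chaperone Kar2 (-1.89), and JEM1, an Hsp40 of that compartment (-1.68). CNE1, the calnexin homologue, was the member that rose (0.21), and SSS1 (-0.05) was not called. The spike-in median was -0.384, with 13 members lower and 5 higher.

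Of 21 targets of Pdr1 and Pdr3, the regulators of multidrug resistance, 19 rose and 2 were lower, 20 and 0 in the spike-in scaling (median 1.17, camera adjusted p = 9.75e-07, and 0.0367 as adjusted p with an estimated correlation). YGR035C rose 8.66-fold, RSB1, a putative sphingoid base transporter, 7.28-fold and GTT2, a glutathione transferase, 6.45-fold. LAC1 and YOR1 were lower in the deposited scaling alone.

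Oxidant defence genes rose as groups with the preset correlation, but their lists share members and are not separate evidence. Also in another list were 11 of the 31 antioxidant enzymes, 9 of the 22 aldehyde and aryl-alcohol genes and 3 of the 21 Pdr1 and Pdr3 targets. Among 29 Yap1 targets 23 rose and 3 were lower, 27 and 0 in the spike-in scaling (median 0.63, camera adjusted p = 2.09e-06; adjusted p = 0.134 with an estimated correlation), and 16 of the 29 also belong to another list. The 3 lower members, FRM2, LOT6 and CCP1, were lower in the deposited scaling alone. Of 31 antioxidant enzymes 20 rose and 7 were lower, 26 and 1 in the spike-in scaling (median 0.39, camera adjusted p = 0.00201; adjusted p = 0.11 with an estimated correlation). CTA1, the peroxisomal catalase, rose 7.95-fold while CTT1, the cytosolic catalase, fell 1.89-fold. Of 22 genes of aldehyde and aryl-alcohol detoxification 15 rose and 5 were lower, 18 and 2 in the spike-in scaling (median 0.40, camera adjusted p = 0.0162; adjusted p = 0.29 with an estimated correlation). ALD5, a mitochondrial aldehyde dehydrogenase, rose 3.81-fold and AAD6 2.94-fold, and AAD10 fell 3.93-fold. GCY1 (-0.85) and GLO1 (-0.79) were lower, the latter not called in the spike-in scaling, and ALD4 and YPR1 were lower in the deposited scaling alone. Without the dimmest 25% of probe sets this list was not called (adjusted p = 0.255).

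Of 26 genes of sulfur assimilation and methionine synthesis 20 rose and 5 were lower, 23 and 1 in the spike-in scaling (median 1.12, camera adjusted p = 8.99e-06; adjusted p = 0.11 with an estimated correlation), among them SUL1, MET3, the ATP sulfurylase (5.36-fold), and MET28, a transcription cofactor (4.41-fold). SAM3, an S-adenosylmethionine permease, fell 2.13-fold, and CYS3, MUP1, MET8 and SAM2 were lower in the deposited scaling alone. Of 38 Gcn4-controlled genes for amino acids other than lysine 32 rose and 3 were lower, 36 and 2 in the spike-in scaling (33 and 3 adjusted over the list alone; median 0.81, camera adjusted p = 2.12e-08; adjusted p = 0.143 with an estimated correlation). LEU1, isopropylmalate isomerase, rose 5.58-fold, BAT1, the mitochondrial branched-chain aminotransferase, 4.73-fold, and ARG7 3.50-fold, while ARG3, ornithine carbamoyltransferase, fell 2.36-fold. ILV6 (-0.93) fell too, and ARG8 was lower in the deposited scaling alone. LEU2, which this strain lacks, counts among the 32 at 5.39 in methanol and 5.64 in LoaOOH, near the brightest negative control (5.146).

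Of 10 lysine biosynthesis genes measured, 6 were lower, 1 higher and 3 not called, and camera did not call the list (median -0.26, adjusted p = 0.0875; fry down, adjusted p = 8.55e-05; spike-in median 0.261, with 3 lower and 5 higher). LYS9, saccharopine reductase, fell 2.85-fold, LYS4, homoaconitase, 2.03-fold, and LYS12, homoisocitrate dehydrogenase, 2.001-fold. LYS2 (-0.61) lost its call in the spike-in scaling, where LYS1 (-0.39) and LYS14 (-0.10) turned positive at 0.13 (not called) and 0.41 (adjusted p = 0.00372). LYS14 was barely called (adjusted p = 0.0445) and lost the call without any 1 of the 6 arrays (adjusted p = 0.0541 to 0.137) and with centring, array weights or a variance trend (0.0525 to 0.14). LYS5, which activates the Lys2 enzyme, rose by 0.46. LYS20 (0.07), LYS21 (-0.12) and ARO8 (-0.13) were not called. Other settings called ARO8 (adjusted p = 0.0196 with quantile normalisation and 0.00371 with array weights) and LYS21 (0.00808 with array weights), both lower, and the spike-in scaling called them higher, at 0.39 each (adjusted p = 0.00596 and 0.00572), along with LYS20 (0.59, adjusted p = 3.39e-05). Without methanol replicate 3 camera called the list (median -0.332, adjusted p = 0.0423), and ARO8 and LYS21 were then called as well (adjusted p = 0.0382 and 0.00395), as was ARO8 without LoaOOH replicate 1 (0.0183).

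Of 30 genes of the Aft1-controlled iron regulon 23 rose and 5 were lower, 26 and 3 in the spike-in scaling (median 0.74, camera adjusted p = 6.5e-06; adjusted p = 0.11 with an estimated correlation). FIT2, HMX1 and ISU2 led it. The 5 lower members were BIO5 and VHT1 (-1.68), which carry biotin precursors and biotin, FET4 (-1.04), a low-affinity iron transporter, FIT1 (-0.54), which lost its call in the spike-in scaling, and FRE2 (-0.21), which was lower in the deposited scaling alone.

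Of 27 genes of beta-oxidation and the peroxisome 20 rose and 5 were lower, 23 and 1 in the spike-in scaling (median 0.28, camera adjusted p = 0.00342; adjusted p = 0.216 with an estimated correlation), and the list was not called without the dimmest 25% of probe sets (adjusted p = 0.0625). CRC1, the mitochondrial acetyl-carnitine carrier, rose 5.98-fold and FAA2, a peroxisomal acyl-CoA synthetase, 4.07-fold, and PEX14, a receptor-docking peroxin, fell 1.87-fold. PEX19 (-0.65) was not called in the spike-in scaling, and DCI1, CIT2 and PEX13 were lower in the deposited scaling alone. Of 26 ergosterol genes 16 rose and 6 were lower, 21 and 1 in the spike-in scaling (median 0.30, camera adjusted p = 0.0154; adjusted p = 0.27 with an estimated correlation), with ERG3 at 2.73-fold, the sterol regulator UPC2 at 2.57-fold and ERG20 lower by 1.82-fold. Of 19 genes of fatty acid synthesis, elongation and desaturation 12 were lower and 4 higher (median -0.18, camera adjusted p = 0.131; fry down, adjusted p = 8.7e-05; spike-in median 0.335, with 0 lower and 11 higher). FAA4 (-0.75) and FAS2 (-0.53) fell in the deposited scaling and were not called in the spike-in scaling, and SPT23, ELO2, ACS2 and ELO1 were the higher members.

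Of 39 proteasome genes 24 rose and 6 were lower, 35 and 0 in the spike-in scaling (median 0.20, camera adjusted p = 0.00108; adjusted p = 0.122 with an estimated correlation), led by their activator RPN4 at 2.38-fold, with PRE8 at 1.93-fold and PUP1 at 1.87-fold. Of 42 genes of the respiratory chain and ATP synthase 26 rose and 6 were lower, 37 and 0 in the spike-in scaling (median 0.26, camera adjusted p = 0.00428; adjusted p = 0.198 with an estimated correlation, and 0.093 in the spike-in scaling). COX7 rose 1.98-fold and CYC1, cytochrome c, 1.88-fold.

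Of 108 ribosome biogenesis genes 71 were lower and 15 higher (median -0.28, camera adjusted p = 0.00077; adjusted p = 0.729 with an estimated correlation, which was 0.649 in this list). In the spike-in scaling the median turned to 0.238, with 46 higher and 15 lower. RPF2, a factor of large subunit assembly, fell 2.74-fold and NOP16 2.17-fold, while NOC4 rose 2.02-fold. Of 127 cytosolic ribosomal protein genes 32 were higher and 49 lower (30 and 47 adjusted over the list alone; median -0.03, camera adjusted p = 0.489; fry down, adjusted p = 0.0015; spike-in median 0.484, with 94 higher and 1 lower). RPL19A fell 1.82-fold.

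General stress genes were called by fry, in opposite directions, and not by camera. Of 25 heat shock genes under Hsf1 13 were higher and 7 lower, 20 and 0 in the spike-in scaling (median 0.13, camera adjusted p = 0.126; fry up, adjusted p = 0.00768). BTN2, an aggregate sorting factor, rose 3.49-fold, and the Hsp90 partners AHA1 and CPR6 rose 1.80-fold and 1.69-fold. Of 34 environmental stress genes under Msn2 and Msn4 19 were lower and 8 higher (median -0.23, camera adjusted p = 0.0961; fry down, adjusted p = 0.00768; spike-in median 0.29, with 2 lower and 17 higher), and camera called them lower without methanol replicate 3 (adjusted p = 0.0366). XBP1, a repressor made under stress, fell 2.34-fold and GRE1 rose 1.64-fold. The pentose phosphate list held 4 higher and 4 lower of 11 (median -0.05, camera adjusted p = 0.791; fry down, adjusted p = 0.00613; spike-in median 0.467, with 8 higher and 2 lower), with TKL2, a minor transketolase, lower by 2.79-fold and ZWF1, which makes NADPH, higher by 1.22-fold. SOL3, RPE1 and TKL1 were also higher, and NQM1, GND2 and RKI1 lower, of which RKI1 turned positive in the spike-in scaling and GND2 lost its call.

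Camera called neither list of markers of other cell types. Of 25 haploid and mating genes 7 were higher and 9 lower (6 and 9 adjusted over the list alone; median -0.06, camera adjusted p = 0.659; fry down, adjusted p = 0.0031; spike-in median 0.458, with 16 higher and 4 lower), with FIG1 lower by 2.19-fold and AXL1 by 1.93-fold. Of 29 meiosis and sporulation genes 12 were higher and 9 lower, with a median of -0.0124, a mean of 0.0272 and a camera test that pointed up (adjusted p = 0.685; fry adjusted p = 0.177); the median was 0.0209 with arrays centred on their medians and 0.506 in the spike-in scaling, with 22 higher and 3 lower. MND1, a meiotic recombination gene, rose 3.85-fold and IME1, the inducer of meiosis, 2.48-fold.

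**Figure D3:**
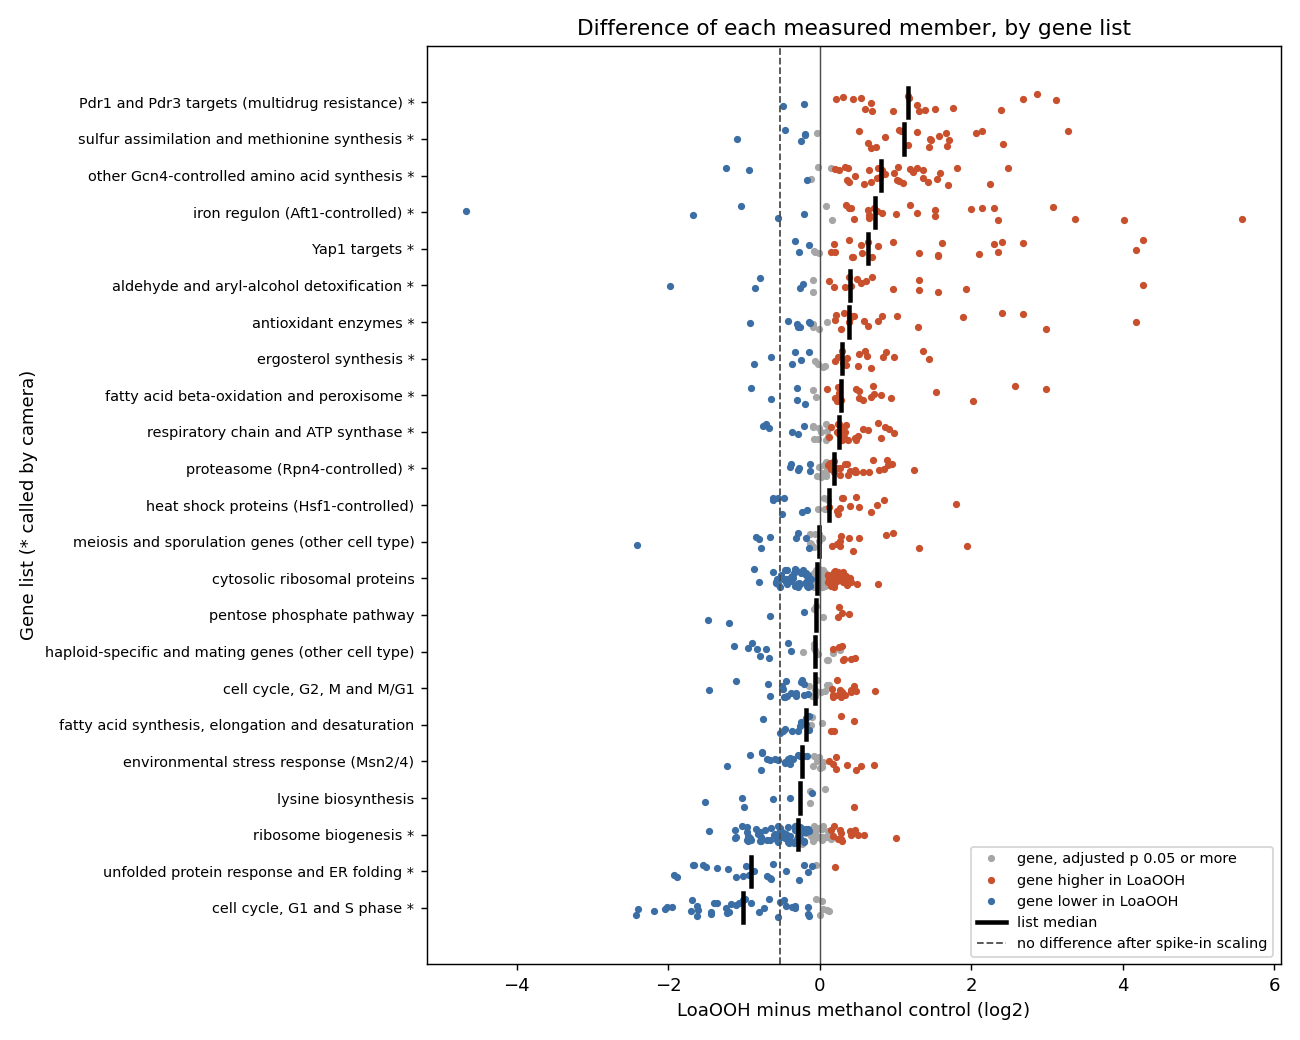
Log2 difference, LoaOOH minus methanol (x axis), of each measured member of the 23 gene lists (y axis, sorted by median; asterisks mark the 14 lists called by camera), coloured by the direction called by limma, with the list median as a black bar. The solid line is no difference in the deposited scaling and the dashed line no difference in the spike-in scaling; the medians of G1 and S phase (-1.01) and of the unfolded protein response (-0.90) lie below both lines, and 9 list medians that lie between the lines turn positive in the spike-in scaling.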

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

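The tests in this part were chosen only after the result was seen, apart from the test of gene length.

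Probe sets without a gene in the annotation also differed. Of 218 such probe sets 162 were called by limma, 69 higher and 93 lower, with 15 at least 2-fold higher and 7 at least 2-fold lower in the LoaOOH arrays. They were fitted and adjusted on their own, so their calls are not on the same footing as those of the 5498. Otherwise they enter only the alternative that adds them. The largest rise was 8.07-fold (log2 difference 3.01, SE 0.0587) and the largest fall had a log2 difference of -1.88.

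The breadth of the response, 4327 of 5498 probe sets, was set against chance and against gene length. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05: 1 split, the real one, gave as many calls, and the highest of the others gave 0 by limma (32 probe sets at an unadjusted p under 0.05, against 4395 for the real split). Shorter genes were higher, with a Spearman rho of -0.128 across probe sets, which are not independent, and a median log2 difference of 0.101 in the shortest and -0.0953 in the longest of 5 length classes. Removing each array's trend with gene length left 4356 calls, of which 3983 were calls with the same direction before, so a length bias as the whole cause is argued against. A response to LoaOOH is the explanation that the design names, and no test here separates it from the grouping itself.

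Spike-in and ribosomal RNA probe sets were lower in the LoaOOH arrays. A change in scanning or RMA scaling is argued against by the hybridisation controls, which moved by -0.0156 against -0.518 for the spike-ins. Those controls are added after labelling, so they do not bear on a difference in labelling, which stays open. The 3' minus 5' difference of the dap spike-in, which is added to the RNA, did differ. It was 1.68 (SD 0.14) in the methanol arrays and 2.08 (SD 0.034) in the LoaOOH arrays (exact permutation p = 0.1). Whether a labelling difference lowered the spike-in and ribosomal RNA signals was not tested. An unequal amount of spike-in mix as the whole cause is argued against by the ribosomal RNA, which is not in that mix and moved by -0.639. A larger share of polyadenylated RNA in the total RNA of LoaOOH cultures, which could lower both classes alike, stays open: the ribosomal RNA moved by -0.121 relative to the spike-ins, with an SD of 0.0829 between arrays of a group, which is too close to decide. If that were the cause, most messages would be higher per unit of total RNA, as in the spike-in scaling with its 3625 higher and 422 lower.

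The iron regulon was weighed because FIT2 and HMX1 were among the largest rises. Signal near background is argued against, since 22 of the 23 members called higher had a LoaOOH mean over 1 log2 unit above the brightest negative control. In many organisms low iron is met by lower expression of iron-containing enzymes, and such a fall might accompany the rise here. The 24 iron-containing enzymes other than BIO2 had a median log2 difference of 0.088 (0.606 in the spike-in scaling, against such a fall). Of these, 12 were higher and 11 lower, and 17 belong to the 23 lists, whose values had been seen. The SE of this median, 0.277, came from the spread over the genes taken as independent, not from the spread between cultures. With the scaling open the test does not decide. It also cannot separate such a fall from the changes of other lists that share its members, such as LEU1 (2.48) and PRI2 (-1.69). An effect of LoaOOH on iron sensing remains an untested hypothesis.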

How the results depend on the processing

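The spike-in scaling, the added unnamed probe sets and the filter at the brightest negative control are tests chosen only after the result was seen. A filter on the S. pombe probe sets was not run, because the annotation did not tell them apart.

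Across all alternatives but treat, the count of called probe sets stayed between 3324 (without the dimmest 25%, fewer probe sets tested) and 4575 (array weights, whose estimate stopped before convergence). Treat against a log2 change of 0.5, a stricter null, called 1221, 581 higher and 640 lower. Differences of at least 2-fold numbered 319 without the dimmest 25%, against 504 in the main test. This is a steeper drop than that of all calls, from 4327 to 3324, so such differences were more frequent among the dimmest probe sets. In the spike-in scaling they numbered 959, with 3625 probe sets called higher and 422 lower because every difference moves up by 0.518. Camera with an estimated correlation called 3 lists and fry, which compares no list with other genes, called 22; other alternatives called 12 to 16.

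Without each array in turn, 4053 to 4279 probe sets were called, 500 to 532 at least 2-fold, and 14 to 16 lists. Between 4030 and 4164 of the calls were shared with the 4327, and 0 of those shared changed sign.

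In the spike-in scaling FRM2 (0.19), LAC1 (0.029), RPT4 (0.13), IFA38 (0.037), LYS1 (0.13), LYS14 (0.41), ARO8 (0.39) and LYS21 (0.39) turned positive, by the added shift, and 14 of the 100 named genes lost their call, FRM2, LAC1, RPT4, IFA38 and LYS1 among them. Quantile normalisation turned LYS20 to -0.032 (adjusted p = 0.638, not called in either); the cause was not tested. Without variance moderation RPL41A lost its call (adjusted p = 0.0547), and treat ended 18 calls of named genes.

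With the replicate number as a block 4453 probe sets were called, 504 at least 2-fold, and 14 lists, and ARO8 gained a call (adjusted p = 0.0277). The deviations of arrays with the same number correlated at 0.31, 0.0491 and 0.258, which does not settle whether the numbers pair the cultures. LoaOOH replicates 1 and 3 correlated best with the methanol replicate of the same number, and LoaOOH replicate 2 with methanol replicate 3 (0.13). Signal limits the dimmest genes: folds of RGI2 and SUL1 are bounds. LEU2, which the strain lacks, measured 5.39 in methanol and 5.64 in LoaOOH. The methanol means of YHK8 (5.47) and MND1 (5.46) and the LoaOOH mean of FIG1 (5.26) lay near or below that level, so their folds may be bounds too.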

Other observations

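The test of Leu3 targets was chosen only after the result was seen, and the gene sets of this part were picked after single members had been noticed. Camera's p-values in this part were adjusted over these sets and the iron-containing enzymes together, not over the 23 lists.

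Some permease genes for nitrogen sources and some genes that glucose represses were among further changes. The ammonium permease genes MEP1 (log2 difference -1.86) and MEP2 (-1.57), the general amino acid permease GAP1 (-1.61), the peptide transporter PTR2 (-1.98) and the proline permease PUT4 (-1.66) fell, by limma at adjusted p-values of 1.36e-09 to 8.39e-08, while CAR1, arginase, rose 3.90-fold. In contrast JEN1 (3.75), SPG4 (3.10), CRC1 (2.58) and the glucose transporter HXT2 (2.53) rose.

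The genes that glucose represses may have risen more widely. With JEN1, SPG4, CRC1, HXT2, RGI2, ADR1 and HXK1 left out, as their values had been seen, the 20 other members measured had a median log2 difference of 0.978, with 16 higher and 2 lower (camera adjusted p = 2.27e-05, and 0.031 as adjusted p with an estimated correlation). Of the 20, CAT8, a regulator (1.57), and SUC2, invertase (1.48), were higher. The lower members were HXT7 (-0.47), lower in the deposited scaling alone, and SFC1, whose LoaOOH mean (5.07) lay below the brightest negative control (5.146). By contrast a wider fall of genes under nitrogen catabolite repression could not be settled. With MEP1, MEP2, GAP1, PTR2, PUT4, CAR1 and BAT2 left out on the same ground, the 18 other members had a median of -0.265 (0.254 in the spike-in scaling), with 11 lower, MEP3 (-1.10) and the urea transporter gene DUR3 (-1.56) among them, and 3 higher (camera adjusted p = 0.0585; 0.154 as adjusted p with an estimated correlation).

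The targets of Leu3, a regulator of branched-chain amino acid synthesis, might account for LEU1, BAT1 and OAC1 (2.85), which stays open. The 6 other targets measured had a median of 1.07, with 5 higher (camera adjusted p = 0.00724; 0.154 as adjusted p with an estimated correlation), but 4 of the 6 belong to the Gcn4 list, whose values had been seen. LEU2, which is deleted in this strain, is counted among the 5.

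Several biotin genes were lower: beside BIO5, BIO3 and BIO4, BIO2, biotin synthase, fell by 1.58 or 3.00-fold, VHT1 fell by 1.68, and BPL1, the biotin ligase, was lower at -0.24 in the deposited scaling alone. No test of them as a group was made. URA3, also deleted in BY4743, measured 3.50 in methanol and 3.37 in LoaOOH, below the brightest negative control, and HIS3, of which the strain keeps part, rose 2.69-fold.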
